A study of Mus musculus with 6 samples.

How the data were processed

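The study measured poly(A)-selected RNA from pancreatic islets of 3 control and 3 bKO mice with paired-end sequencing. Per the labels, reads were aligned to GRCm38 with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3. The submitters' processing notes also name DESeq2 1.20.0 and CASAVA as tools the authors used, with no role given. The strand setting, the handling of reads with several matches and the annotation release were not given in the sources used here.

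The deposited table holds FPKM, fragments per kilobase of gene length scaled to library size, for 54532 genes, with gene lengths, positions and biotypes. Every value above 0, multiplied by the gene's length and 1 factor per library, came to a whole read within 0.01 (100% of values), so the deposited FPKM keep the read counts and the depth is known. The factors equalled median-of-ratios size factors times the geometric mean of the library totals (size factors 0.923, 0.988 and 0.929 in control, 1.10, 1.04 and 1.06 in bKO). The authors' FPKM are therefore scaled by size factors and not by the library totals. Recovered totals ran from 16863329 to 18240339 reads, and intervals and floors made from reads cover counting error only. The tables were read through the column labels, and 0 columns of other samples were present.

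Groups were taken from the genotype labels. Libraries of one group differed beyond sampling noise, with a chi-square per degree of freedom of 4.09 to 6.50, so none was treated as a repeat of another. The planned test for counts was not used because the values are FPKM. As planned for that case, limma 3.58.1 (R 4.3.3) was fitted to log2(FPKM + 1) with bKO against control and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The filter (FPKM of at least 0.5 in at least 3 libraries, leaving 15717 genes) and the mean-variance trend in the empirical Bayes step were set after the unit was known and before any result was seen. Fold changes on the log2(FPKM + 1) scale understate the change of low genes. Shares of reads were compared with a two-sided exact permutation test, for which 3 against 3 libraries give no p below 0.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

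28 gene lists were fixed before the data were examined and tested with camera with a preset correlation of 0.01, then with an estimated correlation, and with fry. Camera compares a list with the other genes, and fry tests whether a list's genes move on balance one way. With an estimated correlation camera tests on the 4 residual degrees of freedom, so its p-values rise even where the estimate is not positive. A count of changed members adjusted over the list alone stands beside that over all genes tested. Genes were named by a rule also fixed before the data were examined. It took Ythdc1, the 10 largest rises and the 10 largest falls among called protein-coding genes with a mean CPM of at least 5 from recovered reads and groups that do not overlap, predicted genes left out. It also took up to 4 members of each list with the smallest adjusted p, and Ins1, Ins2, Slc2a2, Mafa, Pdx1, Ucn3, Gcg and Sst. Some genes that the rule or a test took are not reported here.

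The limma step was tested on simulated reads for 15825 genes of the bKO against control comparison, with means and library sizes of these data. It recovered 68.7% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 95.4% of those changed 4-fold. 16 of its 173 calls were false, above the nominal 5%, and the simulated dispersion of 0.0014 is probably lower than that of genes with few reads. Camera gave p under 0.05 for 3 of 100 simulated lists without a change. The simulated genes were drawn independently, so this does not test camera on lists whose genes vary together.

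Gene positions are those of the table, on GRCm38. 54495 of the gene IDs were found in GENCODE vM21, 53585 of them with the same start and end, and that annotation was used to find overlapping genes. Alternatives fixed in advance were scaling by library totals, no filter, a CPM of at least 1 in at least 3 libraries, the replicate number as a block, leaving out acinar and hormone genes, an acinar covariate, a log2 fold change of at least 1, and leaving out each library. Alternatives chosen after seeing the data were pseudocounts of 0.1 and 0.5, voom on recovered reads, quantile normalization and an FPKM of at least 1 in at least 3 libraries. Tests made for counts alone were not run, and the median-of-ratios alternative is the scaling the values already carry.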

Results

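Gene expression was measured by poly(A)-selected RNA sequencing in pancreatic islets, the endocrine cell clusters of the pancreas, from mice aged 7 weeks. 3 libraries came from mice with floxed Ythdc1 and no deletion (control) and 3 from mice with a beta-cell knockout of Ythdc1 (bKO). Beta cells are the insulin-producing cells of the islet, and the samples were whole islets, which also hold alpha, delta and PP cells, vessels and immune cells. The labels call the replicates independent biological samples. The reads recovered from the deposited values came to 17315724, 18240339 and 16863329 in the control libraries and to 17770058, 17145960 and 17319353 in the bKO libraries. The first principal component held 49.9% of the variance and separated the groups.

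The comparison asks how islet gene expression differs when beta cells lack YTHDC1, a nuclear protein that binds N6-methyladenosine (m6A) in RNA. Ythdc1 itself (ENSMUSG00000035851, chromosome 5, 86804221 to 86836659, GRCm38) was listed at 5.76, 6.46 and 6.18 FPKM in the control libraries and at 3.81, 3.79 and 3.87 FPKM in the bKO libraries. It fell by 0.56 on the log2 scale (SE 0.058, limma adjusted p = 0.0014), to 0.624 of the control mean. The value covers all exons of the gene and all cells of the islet, so it does not measure the deletion in beta cells. The free-text descriptions of bKO replicates 2 and 3 name other Ythdc genes, while their genotype label gives Ythdc1, and Ythdc1 was low in both.

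Islets of bKO mice had less mRNA of the beta-cell transcription factor Mafa and of Slc2a2, the glucose transporter GLUT2, and more mRNA of the peptide hormone genes Vip and Adm2 and of Aldh1a3, a retinaldehyde dehydrogenase known as a marker of dedifferentiated beta cells. Mafa (chromosome 15, 75745490 to 75748228) fell from 423 ± 31 to 145 ± 18 FPKM (SD, n = 3 per group). Slc2a2 (chromosome 3, 28697903 to 28731359) fell from 172 ± 6.1 to 74.1 ± 2.3 FPKM, and Aldh1a3 (chromosome 7, 66390890 to 66427517) rose from 0.552 ± 0.13 to 16.0 ± 4.3 FPKM. In lists fixed in advance, 9 of 14 p53 response genes and 10 of 12 immediate early genes rose, while 10 of 20 proliferation, 8 of 13 macrophage and 9 of 24 respiratory chain genes fell. With limma and Benjamini-Hochberg adjustment, 3192 of 15717 tested genes changed, 1408 higher and 1784 lower in bKO, and 158 and 74 of them by at least 1 on the log2(FPKM + 1) scale. When libraries were scaled by their total in place of size factors, 3684 genes were higher and 737 lower, a share of 83.3% higher against 44.1%. With a pseudocount of 0.1 the genes past 1 on the log2 scale were 364 and 166, and with voom on recovered reads 440 and 194.

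**Figure D1:**
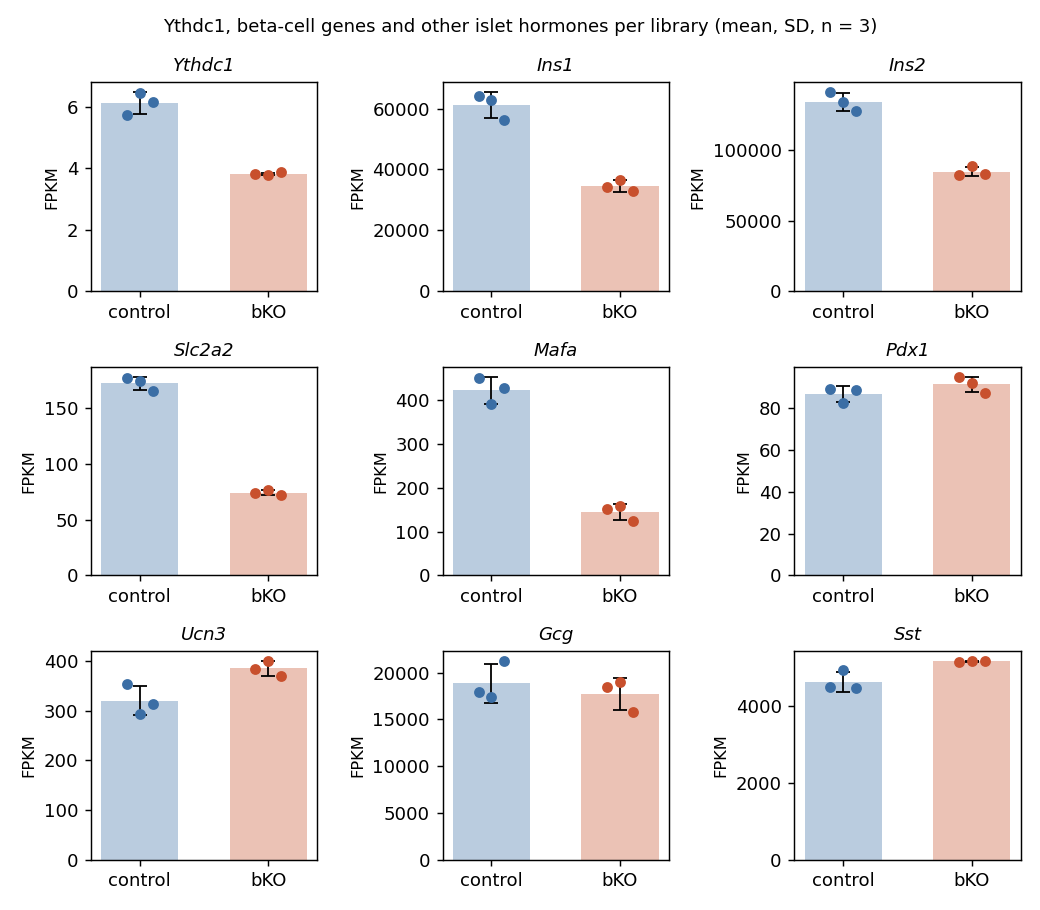
FPKM of Ythdc1 and 8 islet genes in each library (points), with the group mean (bar) and SD (error bar), 3 libraries per group. Ythdc1, Ins1, Ins2, Slc2a2 and Mafa lie lower in every bKO library than in every control library, while Gcg overlaps between the groups.

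Among abundant protein-coding genes, the largest rise on the log2(FPKM + 1) scale was that of Vip, vasoactive intestinal peptide (chromosome 10, 5639218 to 5647617). Vip had 0 reads in the 3 control libraries and 12.0 ± 2.9 FPKM in bKO, at least 673-fold higher against a floor of 3 reads over the control group. Col20a1, a collagen gene, rose from 1.36 ± 0.18 to 28.4 ± 1.5 FPKM, and Adm2, adrenomedullin 2, rose from 0.189 ± 0.086 to 13.3 ± 1.5 FPKM. Nupr1, a stress-induced transcriptional regulator, rose from 4.70 ± 0.56 to 52.99 ± 2.8 FPKM, and Spp1, osteopontin, from 10.1 ± 1.9 to 73.1 ± 6.1 FPKM. Tgm7 had 1 read in the control libraries together and 592 in bKO, a ratio of 525 with a 95% counting interval of 93.9 to 20786 (exact binomial). Serpina7, Nrsn1 and Aass rose by 2.53, 2.40 and 2.03 on the log2 scale. The largest falls on the log2(FPKM + 1) scale were those of Fam151a, from 31.5 ± 1.4 to 5.82 ± 1.8 FPKM, and Trpm5, a calcium-activated cation channel, from 14.8 ± 1.4 to 2.74 ± 0.74 FPKM. Tmem215 fell by 1.67, Prss53 by 1.61, Cyp4f39 by 1.53 and Mlph by 1.46 on that scale, while the ratio of FPKM means was lowest for Mlph, at 0.172 against 0.185 for both Fam151a and Trpm5. Cd79a, a subunit of the B-cell receptor, fell from 5.84 ± 1.6 to 1.27 ± 0.48 FPKM, and Lyve1, a receptor of lymphatic endothelium and some macrophages, from 5.85 ± 0.46 to 1.29 ± 0.13 FPKM. Srp54b fell by 1.58 on the log2 scale, and its value is uncertain because near-identical copies can share its reads. Ythdc1, Col20a1, Spp1, Fam151a, Trpm5, Prss53 and Slc2a2 overlap other annotated genes, and no strand setting was given for the counting.

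**Figure D2:**
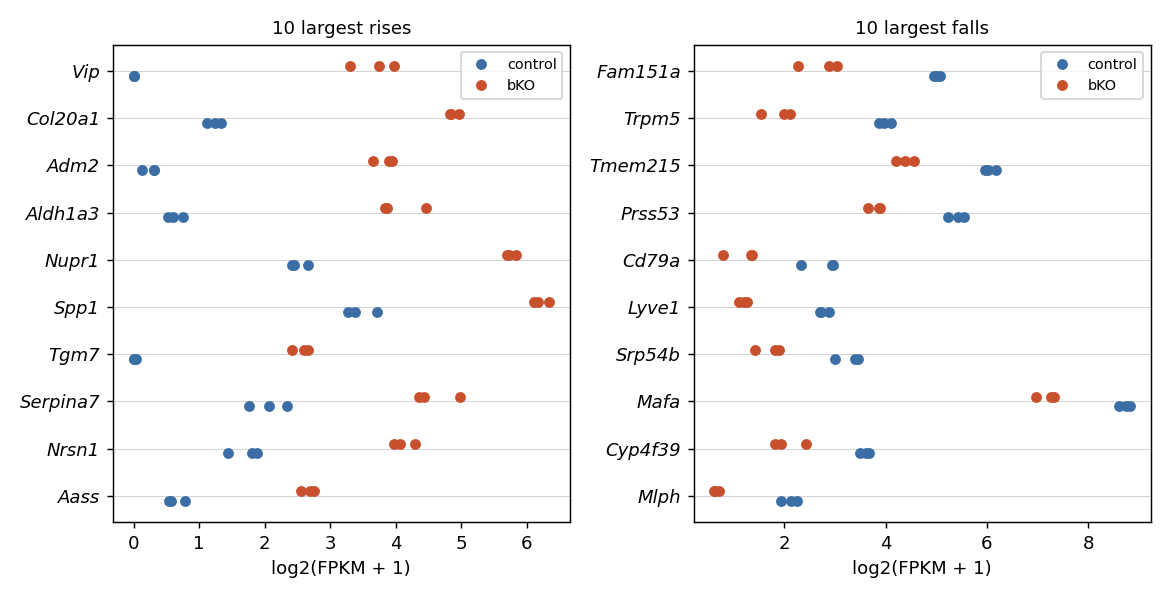
Expression as log2(FPKM + 1) in each library (points) for the 10 genes with the largest rises and the 10 with the largest falls under a rule fixed in advance, 3 libraries per group. For each gene the bKO and control points do not overlap, which the rule required.

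Both insulin genes fell. Ins1 went from 61085 ± 4260 to 34529 ± 1835 FPKM (log2 fold change -0.82, limma adjusted p = 0.0091) and Ins2 from 134303 ± 6487 to 84754 ± 3347 FPKM (log2 fold change -0.66, limma adjusted p = 0.046). Together they took 22.5% ± 0.82 of the reads in control and 15.6% ± 0.51 in bKO (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). The call of Ins1 was lost without bKO replicate 1 (-0.82, limma adjusted p = 0.057), with no filter and with quantile normalization. That of Ins2 was lost without control replicate 1 or 3 or any bKO library, with log2 fold changes of -0.70 to -0.63 there, and with no filter, a CPM filter, a pseudocount of 0.5 and quantile normalization. The limma SE of Ins1 and Ins2, 0.14 and 0.18, are drawn toward the mean-variance trend and are wider than the spread of the libraries alone gives. Their p-values therefore do not measure replicate spread alone. Both genes stayed called with voom on recovered reads.

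Genes of glucose uptake and sensing fell as a list. Of 19 measured members, 9 fell and 1 rose (12 and 3 adjusted over the list alone), with camera adjusted p = 0.0017 and adjusted p = 0.23 with an estimated correlation. Beside Slc2a2 and Trpm5, Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase, fell by 1.04 and the fatty acid receptor gene Ffar1 by 1.03 on the log2 scale. Of 25 genes of insulin processing and secretion, 10 fell and 5 rose, the same numbers adjusted over the list alone, and camera did not call the list (adjusted p = 0.054). Sytl4, a granule exocytosis factor, fell by 1.32, the zinc transporter gene Slc30a8 by 0.80 and the prohormone convertase gene Pcsk1 by 0.57, while Chgb, chromogranin B, rose by 0.62. Of 17 beta-cell identity genes, 6 fell and 3 rose (7 and 6 adjusted over the list alone). Camera did not call the list (camera adjusted p = 0.56), while fry did (fry adjusted p = 0.014). Nkx6-1 fell from 220 ± 12 to 168 ± 1.7 FPKM, and Pax6 and Neurod1 fell by 0.26 and 0.31 on the log2 scale. Pdx1 was at 87.0 ± 3.9 FPKM in control and 91.5 ± 3.7 in bKO (limma adjusted p = 0.34). Ucn3, a maturity marker, rose from 321 ± 30 to 385 ± 15 FPKM (limma adjusted p = 0.041). The calls of Pax6 and Neurod1 were lost when libraries were scaled by their total (limma adjusted p = 0.11 and 0.057), and that of Ucn3 without control replicate 2 or 3 or any bKO library (log2 fold change 0.21 to 0.30), with no filter and with the acinar covariate. That of Neurod1 was also lost with quantile normalization (limma adjusted p = 0.051). Pax6 and Neurod1 stayed called with total scaling when acinar and hormone genes were left out.

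Of 9 endocrine progenitor and dedifferentiation markers, 4 rose and 1 fell (6 and 1 adjusted over the list alone), with camera adjusted p = 0.0026 and adjusted p = 0.23 with an estimated correlation. Beside Aldh1a3, the tetraspanin gene Cd81 rose from 32.8 ± 1.2 to 49.0 ± 1.3 FPKM and Neurog3, the endocrine progenitor factor, from 2.73 ± 0.28 to 3.93 ± 0.26 FPKM, while Sox4 fell by 0.91 on the log2 scale. The call of Neurog3 was lost without bKO replicate 2 (0.36, limma adjusted p = 0.055). Of 15 genes that beta cells normally keep low, 2 rose and 0 fell (1 and 0 adjusted over the list alone), and camera did not call the list (adjusted p = 0.054). Oat was at 6.11 ± 0.60 FPKM in control and 8.02 ± 0.37 in bKO, and its call was lost without control replicate 2 or bKO replicate 2 or 3. The other rise, Acot7, was called in 8 of 17 settings and also lost without control replicate 2 or bKO replicate 2.

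Of 14 p53 target and apoptosis genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with camera adjusted p = 3.6e-08 and adjusted p = 0.23 with an estimated correlation. Gdf15 rose from 0.436 ± 0.12 to 4.07 ± 0.80 FPKM and the cell cycle inhibitor gene Cdkn1a from 11.7 ± 1.7 to 30.2 ± 2.6 FPKM, and Sesn2 and Ccng1 rose by 0.67 and 0.58 on the log2 scale. Mdm2, among the members not called, was at 14.5 ± 0.68 FPKM in control and 15.1 ± 0.22 in bKO (limma adjusted p = 0.47). Of 20 proliferation genes, 10 fell and 0 rose (13 and 0 adjusted over the list alone), with camera adjusted p = 5.7e-06 and adjusted p = 0.23 with an estimated correlation. Mki67 fell from 4.20 ± 0.33 to 1.94 ± 0.21 FPKM, and Ccnb2, Top2a and Ccnb1 fell by 1.06, 0.81 and 0.72 on the log2 scale. Of 23 genes of the unfolded protein response, 8 rose and 4 fell (9 and 4 adjusted over the list alone), with camera adjusted p = 0.055. Chac1 rose by 1.86, Trib3 by 1.79, Ern1 by 0.48 and Asns by 0.42 on the log2 scale. Of 12 immediate early genes, which tissue dissociation can raise, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with camera adjusted p = 2.5e-06 and adjusted p = 0.25 with an estimated correlation. Ier2 rose from 48.8 ± 4.5 to 82.0 ± 6.5 FPKM, and Fosb, Zfp36 and Junb rose by 0.65, 0.46 and 0.35 on the log2 scale.

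Of 24 nuclear-encoded respiratory chain and ATP synthase genes, 9 fell and 0 rose (13 and 0 adjusted over the list alone), with camera adjusted p = 5.7e-06 and adjusted p = 0.23 with an estimated correlation. These changes were small, with a median of -0.16 on the log2 scale, and with libraries scaled by their total the median was 0.01 while the median of all genes moved from -0.01 to 0.13. Cox6c fell by 0.37 on the log2 scale. Mitochondrially encoded mRNAs took 2.07% ± 0.24 of the reads in control and 2.58% ± 0.046 in bKO (SD, n = 3, two-sided exact permutation p = 0.1), and of 13 such genes 1 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.10). Of 12 glycolytic genes 4 fell and 0 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.47), among them Pkm by 0.37 on the log2 scale. The calls of the other falls, Tpi1, Pfkm and Pfkl, were lost with libraries scaled by their total (log2 fold changes -0.02, -0.10 and -0.05). Of 12 fatty acid oxidation genes 1 fell, Cpt2 by 0.43, and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.45). Of 11 oxidative stress genes 1 rose, Hmox1 by 0.62, and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.81).

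**Figure D3:**
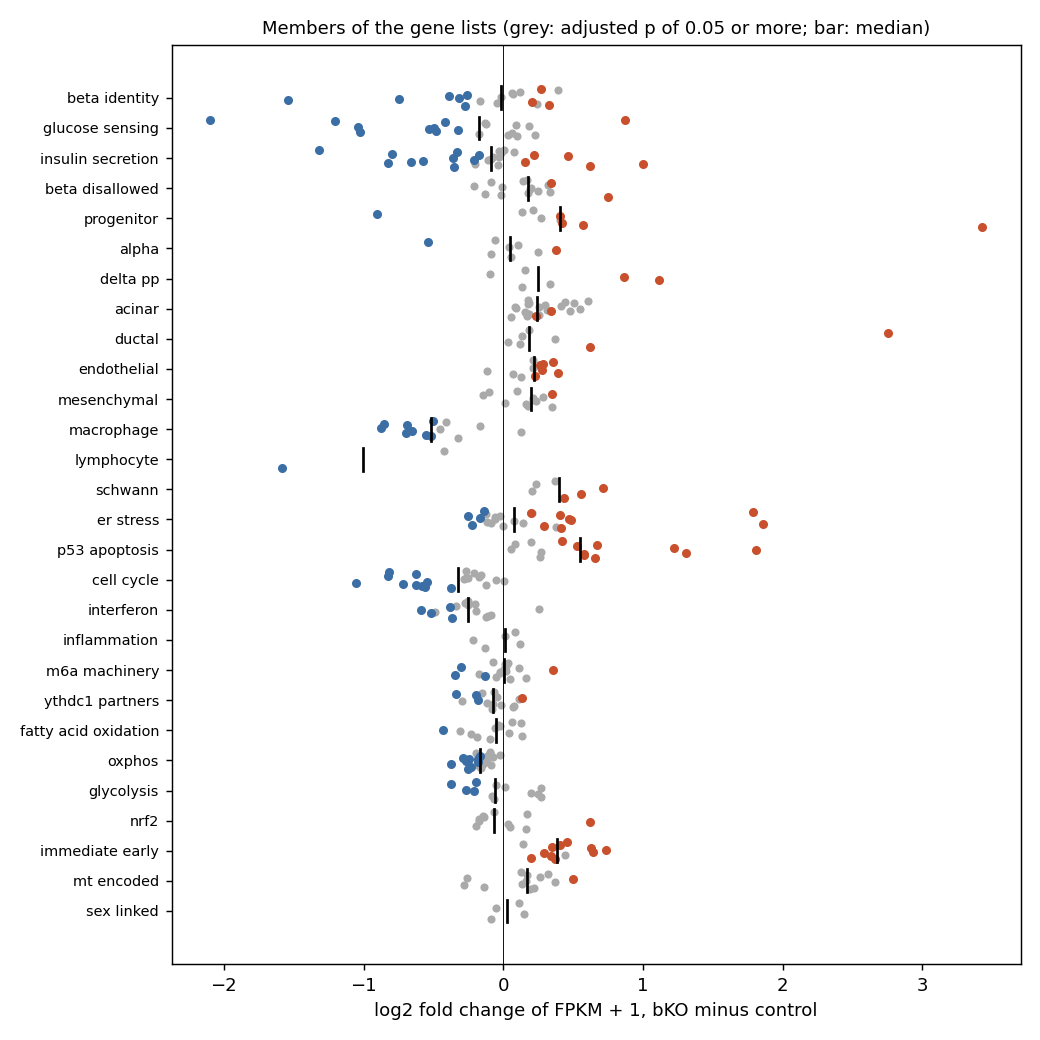
Log2 fold change of FPKM + 1, bKO minus control, for each measured member (point) of the 28 gene lists, with the list median (bar), from 3 libraries per group. Colored points passed limma's adjusted p threshold, red for higher and blue for lower, and 9 of the 14 p53 and apoptosis genes are red while 10 of the 20 proliferation genes are blue.

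Of 6 delta- and PP-cell genes, 2 rose and 0 fell (3 and 1 adjusted over the list alone), with camera adjusted p = 0.037 and adjusted p = 0.40 with an estimated correlation. Ppy, pancreatic polypeptide, rose from 4324 ± 784 to 9330 ± 1340 FPKM and Pyy, peptide YY, from 1635 ± 174 to 2977 ± 251 FPKM. Sst, somatostatin, was at 4621 ± 256 and 5151 ± 10 FPKM. The list's call was lost without control replicate 1 (camera adjusted p = 0.068) and without bKO replicate 3 (camera adjusted p = 0.053), and also without acinar and hormone genes (camera adjusted p = 0.60) and with no filter on low values (camera adjusted p = 0.19), which ended the call of Ppy too (limma adjusted p = 0.15). Of 8 alpha-cell genes 1 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.85). The rise, of Irx2, was called in 10 of 17 settings and lost without control replicate 1 or 2 or bKO replicate 1 or 2. Gcg, glucagon, was at 18836 ± 2118 FPKM in control and 17724 ± 1721 in bKO, and Slc7a2 fell by 0.54 on the log2 scale.

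Of 13 macrophage markers, 8 fell and 0 rose (11 and 0 adjusted over the list alone), with camera adjusted p = 4.3e-05 and adjusted p = 0.25 with an estimated correlation. Ctss, cathepsin S, fell from 24.8 ± 1.2 to 13.1 ± 1.8 FPKM, and the antigen presentation genes Cd74, H2-Ab1 and H2-Aa fell by 0.66, 0.86 and 0.69 on the log2 scale. Of 15 interferon-stimulated genes, 4 fell and 0 rose (8 and 0 adjusted over the list alone), with camera adjusted p = 0.0023 and adjusted p = 0.40 with an estimated correlation. Isg15 fell by 0.59 and Bst2 by 0.37 on the log2 scale, and the call of Isg15 was lost without bKO replicate 2 (-0.56, limma adjusted p = 0.051) and that of Bst2 with libraries scaled by their total (-0.20, limma adjusted p = 0.055), as were those of Ifit1 and Oas1a. Of 2 measured lymphocyte genes Cd79a fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.054). Of 5 measured inflammation genes 0 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.96).

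Of 12 endothelial markers, 6 rose and 0 fell (8 and 0 adjusted over the list alone), with camera adjusted p = 0.0005 and adjusted p = 0.25 with an estimated correlation. Eng and Ptprb rose by 0.39 and 0.29 on the log2 scale. Of 6 Schwann cell markers, 3 rose and 0 fell (4 and 0 adjusted over the list alone), with camera adjusted p = 0.0063 and adjusted p = 0.40 with an estimated correlation. All named Schwann markers were near the filter, Ngfr rising from 0.276 ± 0.087 to 1.10 ± 0.25 FPKM. The other rises, Foxd3 and Cdh19, were called in 6 and 7 of 16 settings. The list's call ended with a filter of 1 FPKM (camera adjusted p = 0.28) and with total scaling (camera adjusted p = 0.059). Of 7 duct markers, 2 rose and 0 fell (3 and 0 adjusted over the list alone), with camera adjusted p = 0.0031 and adjusted p = 0.23 with an estimated correlation. These were Spp1, which other cell types also express, and Ambp, which rose by 0.62 on the log2 scale. Of 12 mesenchymal markers 1 rose, Pdgfrb by 0.35, and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.054). Acinar genes took 0.0271% ± 0.011 of the reads in control and 0.0366% ± 0.0047 in bKO (SD, n = 3, two-sided exact permutation p = 0.3). Of 22 acinar genes 2 rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.044 and adjusted p = 0.76 with an estimated correlation. The acinar call was lost with libraries scaled by their total (camera adjusted p = 0.70), with no filter (0.057), with quantile normalization (0.058) and with the acinar covariate (0.78). It was also lost without control replicate 1 or 2 or bKO replicate 1 or 2. The list's median was 0.24 with all libraries, -0.00 without control replicate 2 and 0.58 without control replicate 3.

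Of 18 other genes of the m6A machinery, 3 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.79). Hnrnpc fell by 0.34 and Wtap by 0.30 on the log2 scale and Rbm15 rose by 0.36, and the call of Wtap was lost with libraries scaled by their total (-0.14, limma adjusted p = 0.076). Hnrnpa2b1 was at -0.13 (limma adjusted p = 0.041), but with libraries scaled by their total it was at 0.05 and with quantile normalization at 0.02. Of 15 splicing, 3' end processing and export factors linked to YTHDC1, 3 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.18), with Srsf7 falling by 0.34 on the log2 scale. The calls of the other falls, Srsf3 and Safb, were lost with libraries scaled by their total (limma adjusted p = 0.69 and 0.91), and Srsf1, the gene that rose, was called in 9 of 17 settings. Xist was listed at 0 in all 6 libraries and the 4 Y-linked genes were measured in both groups, with 0 of them called, also adjusted over the list alone (camera adjusted p = 0.74). The medians and means of the m6A machinery list (0.01 and -0.02), the inflammation list (0.01 and -0.03) and the oxidative stress list (-0.07 and 0.01) differed in sign, and camera's direction was lower for each.

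Of the 28 lists, camera called 13, of which fry called 12, and camera called 0 with an estimated correlation. That loss of calls does not measure correlation between genes alone. For the progenitor list the estimated correlation was -0.11, yet camera p before adjustment went from 0.00082 to 0.025. Fry called 18 lists. Called by fry alone were the lists of beta-cell identity, insulin secretion, genes kept low in beta cells, lymphocytes, unfolded protein response and mesenchymal markers. Their fry adjusted p ran from 0.00027 to 0.043. The groups did not overlap for 40.1% of tested genes, against 10% by chance.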

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

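The pseudocounts, voom, quantile normalization and the filter of 1 FPKM were chosen after seeing the data. A count test and its other scaling, fixed in advance, were not run on FPKM. Ythdc1 stayed lower and called in 17 of 17 settings, with log2 fold changes of -0.68 to -0.42. Mafa, Slc2a2 and Trpm5 also stayed lower and called in 17 of 17, and Aldh1a3 and Vip stayed higher and called in 17 of 17. Scaling by library totals gave 4421 changed genes, 3684 higher and 737 lower, with the median of all genes at 0.13 against -0.01. Leaving out acinar and hormone genes and scaling by totals gave 3103 changed genes, 58.8% of them higher, with the median of the remaining genes at 0.04. The upward shift under total scaling thus came largely with those genes, among which insulin took a smaller share of reads in bKO. Falls lost under total scaling alone are to be read with this shift in mind. Voom on recovered reads called 4358 genes, no filter 2429, a CPM of at least 1 3770, the acinar covariate 2781, quantile normalization 2855, FPKM of at least 1 3156, and pseudocounts of 0.1 and 0.5 3150 and 3180. A log2 fold change of at least 1 left 232 genes by its own construction, and 530 with a pseudocount of 0.1, 369 with 0.5 and 634 with voom.

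Leaving out 1 library, which also leaves fewer samples, gave 1904 to 2783 changed genes, 852 to 1179 higher and 1037 to 1604 lower. The count was lowest without control replicate 1 (1904), and it was 1916 without bKO replicate 1 and 2117 without bKO replicate 2. The higher genes alone came to 937 without bKO replicate 3. The difference in insulin's share of reads ran from -7.32 to -6.50 percentage points, and 11 to 17 lists were called.

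Samples with the same replicate number did not deviate together (correlations across genes of -0.052, -0.014 and -0.073), so the numbers do not pair the samples, and no sample correlated best with its own number. With the replicate number as a block, 2077 genes changed, 925 higher and 1152 lower, and Ins1, Ins2 and Ucn3 were among the genes not called.

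With an estimated correlation 0 of 28 lists were called. Hnrnpa2b1 went from -0.13 to 0.046 with total scaling and to 0.017 with quantile normalization. With total scaling the median of all genes also moved up, from -0.01 to 0.13, so that move is not particular to Hnrnpa2b1. The cause of the move with quantile normalization was not tested. Ins2 was called in 6 of 16 settings and Ins1 in 12 of 16. Quantile normalization gives the most abundant gene the same value in each library, which holds Ins2 at 0. Of lists just over the threshold, the unfolded protein response list passed in 10 of 18 settings, the lymphocyte list in 6, the mesenchymal list and the list of genes kept low in beta cells in 5 each, and the insulin secretion list in 4. Depth limits genes near 0.5 FPKM, where few reads stand behind a value.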

Other observations

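The gene groups and genes below were chosen after their values were seen, and so were the tests, except the count of called lists over other splits of the libraries, which had not been seen. Of 26 measured genes of amino acid and serine synthesis, amino acid transport and stress that are known ATF4 targets, 21 rose and 0 fell (median 0.54 on the log2 scale), and with voom 22 rose and 2 fell. 4 of the 26 are also in lists fixed in advance, among them Sesn2 in the p53 list. No list test is given because the group was put together after values of its members were seen. Phgdh, the first enzyme of serine synthesis, rose from 8.15 ± 0.54 to 23.3 ± 1.7 FPKM (SD, 3 libraries per group) and Psat1 from 2.80 ± 0.27 to 7.36 ± 0.32 FPKM. Slc7a3 rose from 0.117 ± 0.033 to 2.28 ± 0.37 FPKM, and Nupr1 and Chac1 belong to the same group. Of 14 ER folding and degradation factors, all also in a fixed list, 2 rose and 3 fell, with a median of -0.06. With total scaling 5 rose and 0 fell (median 0.11), and with quantile normalization 3 rose and 0 fell (median 0.08), so the falls do not hold under those scalings. Hspa5 went from 410 ± 9.2 to 366 ± 8.4 FPKM and Pdia6 from 182 ± 6.3 to 152 ± 3.9 FPKM, while Herpud1 went from 84.2 ± 7.6 to 117 ± 3.8 FPKM.

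Of 8 measured peptide hormone genes, 1 of which (Gast) is also in the fixed progenitor list, 4 rose and 0 fell, Vip and Adm2 together with Npy, from 1.05 ± 1.0 to 8.99 ± 2.2 FPKM, and Pomc, from 3.69 ± 0.82 to 5.98 ± 0.73 FPKM. Of 11 genes of miRNA processing and silencing, 4 rose and 1 fell (median 0.00). Tnrc6a rose from 14.1 ± 1.3 to 40.7 ± 0.55 FPKM, Tnrc6c from 8.79 ± 0.17 to 25.5 ± 0.77 FPKM and Tnrc6b from 5.19 ± 0.36 to 7.15 ± 0.049 FPKM. Dgcr8 also rose, by 0.30 on the log2 scale, and Dicer1 fell by 0.21, while Ago2 was at 9.89 ± 0.64 and 9.66 ± 0.17 FPKM. The beta-cell enriched enzyme genes Gad1 and Maob fell from 16.8 ± 0.99 to 7.20 ± 0.62 FPKM and from 74.9 ± 3.4 to 31.5 ± 1.7 FPKM, and Areg, amphiregulin, rose from 0.281 ± 0.069 to 6.92 ± 1.2 FPKM.

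Insulin, Mafa and Slc2a2 fell in bKO islets, and a lower share of beta cells in the islets may account for this. Genes largely restricted to beta cells would then fall by about the change of the insulin genes, with a mean of -0.74, but 5 of the 8 other such genes had a 95% interval above it, among them Pdx1, Iapp and Ucn3. Scaling by library totals in place of the authors' size factors left the mean log2 fold change of Ins1, Ins2, Mafa and Slc2a2 at -0.88, against -1.06. Both values argue against these explanations as the whole cause. The first does so only weakly, because the 8 genes were chosen after their values were seen. Lower expression per beta cell in bKO stays open as a hypothesis, as does a smaller loss of beta cells. The control genotype label names only floxed Ythdc1. Loss of YTHDC1 therefore cannot be told apart from other effects of the knockout line, such as those of a Cre transgene.

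Of 40 measured histone genes, whose mRNAs mostly lack a poly(A) tail and whose similar members can share reads, 18 rose and 2 fell (median 0.58, and 0.51 to 0.80 under other scalings and voom). More dividing cells would raise proliferation genes, but the median of that list was -0.33. Genomic DNA in the bKO libraries would add reads alike per kilobase, but silent olfactory and vomeronasal receptor genes gained 0.0885% of the FPKM that histone genes gained. The receptor genes still rose, from 835 reads (0.00293 FPKM) in control to 1373 (0.00427 FPKM) in bKO, with every bKO library above every control library. Pooled histone genes went from 6.42 to 7.94 FPKM, and small RNA genes outside other genes from 853 to 2012 reads. A small background rise in bKO, which would matter for genes with few reads, stays open. More carry-over of RNA without a tail is a candidate explanation that cannot be told apart from a change in histone mRNA. The 4 measured longer RNAs taken as tail-free, Rn7sk, Terc, mt-Rnr1 and mt-Rnr2, had a median of -0.38, too few genes to decide. Of these 3 fell, while Terc was at 0.41 (limma adjusted p = 0.29), and the 514 small RNA genes had a median of 0.28. A change of histone transcripts or their tails in bKO cells stays open and was not tested.

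Macrophage markers and Cd79a fell in bKO islets, and lymphoid tissue carried into the control preparations is a possible explanation for Cd79a. The control libraries held 423 reads of Cd79a, and 7 genes that B and T cells bring with it, such as Ms4a1 and Trac, held 1.65% as many reads, 7 in all (in bKO Cd79a had 104 reads and these genes 60, of which Trac had 36), which argues against tissue with B and T cells as its source. Fewer macrophages in bKO islets would lower all their transcripts alike, and 4 of 13 markers had a 95% interval from voom that missed the list's median of -0.61. Cd68 and Fcer1g lay above it and Ctss and H2-Ab1 below. That just meets the bound of 4, set after the values were seen, at which the count would speak against an even loss. With the bound only just met, fewer macrophages and a change within macrophages cannot be told apart. The antibody light chain gene Igkc fell with Cd79a, from 68 reads to 14 (log2 fold change -1.19, limma adjusted p = 0.040). It held fewer reads than Cd79a in both groups, and antibody-producing cells as a source were not tested.

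The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Every split but the real one puts both genotypes in each group, so a real difference widens their spread and lowers their counts. Only 1 split, the real one, reached the 3192 changed genes, and the highest other count was 2. For higher genes the counts were 1408 and 2, and for lower genes 1784 and 0, again with 1 split as large. For called lists they were 13 and 10, with 1 split as large. A split with both genotypes in each group thus still had 10 lists called by camera with the preset correlation. The 13 list calls therefore stand out less from other splits than the gene counts do. Such groups still differ in their share of each genotype, so the 10 do not give a rate of false calls.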
